A study of Mus musculus with 9 samples.

How the data were processed

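Polyadenylated RNA from mouse left ventricle was sequenced in 9 libraries that fall into 4 groups by genotype and treatment. The knockout is called dSG in the labels, the usual short name of delta-sarcoglycan, which the gene Sgcd encodes. Per the labels' protocols, RNA was extracted with a Qiagen column kit and libraries followed standard Illumina procedures. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

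The authors deposited 1 table of raw read counts per gene for each library. Per the submitters' processing notes, STAR 2.5.2b and HTSeq were used with the mouse build GRCm38; no HTSeq version and no annotation release was named there. The layout of the deposited count tables is that of STAR's gene quantification, with 3 count columns per file, without regard to strand and for each of both strands, and with 4 rows that name no gene. These rows (unmapped, multimapping, outside genes, ambiguous) held 26.6% to 31.9% of the reads and stayed out of library sizes and tests. Reads with several alignments are not counted by STAR's gene quantification, so genes with near-identical copies, such as the hemoglobin genes, are measured by their unique parts. The values are whole-number counts with no normalization.

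By a rule set before the data were examined, as were the groups, tests, gene lists and the alternatives not described below as added, a stranded column was to be used if it held over 2 times the gene counts of the other. The reverse column held 14.5 times the counts of the forward column over all libraries and was used. Counting by strand separates antisense partners. Counts in genes ranged from 21299748 to 31394548 per library. The files listed 49671 gene identifiers, of which 49412 were matched to the GENCODE annotation of GRCm38 for symbols, exonic lengths and coordinates, all given on that build and counted from 1.

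Replicates were compared before they were averaged. A chi-square test of counts gave 15.0 to 93.2 per degree of freedom for the 6 pairs of libraries within groups, so no library was a second copy of another of its group.

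Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after TMM normalization and the filterByExpr filter, which left 15261 genes. The model had 1 coefficient per group and all 9 libraries shared the estimate of the spread. The groups differed in spread, taken as the variance of a mean of 2 log2 CPM values. It was 0.163 in KO vehicle, 0.0944 in WT vehicle, 0.0694 in KO ifetroban and 0.0501 in WT ifetroban. Tests within wild type may therefore be conservative, and those with KO vehicle lenient. The 7 contrasts were each knockout group against the wild-type group of the same treatment, ifetroban against vehicle within each genotype, the interaction, the genotype effect averaged over treatments and the ifetroban effect averaged over genotypes. Tests were two-sided, p values were adjusted by the Benjamini-Hochberg method over the tested genes, and an adjusted p under 0.05 was called. Fold changes are on the log2 scale and were shrunk by edgeR's prior count of 0.125. Their standard errors were calculated back, as the absolute fold change divided by the square root of the F statistic, and are approximate. Levels in CPM, counts scaled to the TMM library size, are given as mean ± SD over the n libraries of a group. CPM is not corrected for gene length, so CPM values compare libraries, not genes.

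Gene lists of pathways and of markers of cell types that ventricle tissue or its dissection could hold were also tested, 45 listed and 44 with at least 5 tested members. The test was camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 44 lists. Camera asks whether the members of a list move one way more than other genes do. Camera with a correlation estimated from each list, and fry, which asks whether members move on balance one way without comparison with other genes, were the alternatives. Further, 25 genes of heart failure, the sarcoglycan complex and thromboxane signalling were fixed in advance, and counts over them are also given as adjusted over the list alone.

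The genes named in each comparison follow a rule. Up to 10 in each direction with the largest log2 fold change were taken among called genes with a mean log2 CPM of at least 1 and, for contrasts of 2 groups, CPM values that did not overlap. Gene models without a proper name, pseudogenes and mitochondrial genes were left out. Where no gene was called, the 3 with the smallest p in each direction are given as values only. The fixed genes and up to 4 members with the smallest p from each described list were added. Other genes are marked as chosen after their values were seen.

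Each script was tested on simulated counts drawn for the 15261 tested genes with the means, library sizes and dispersions of the real libraries. The dispersion of a gene was the same in all groups, unlike the real spread. In these counts 200 genes were changed, 100 of them by 2-fold and 100 by 4-fold. For KO vehicle against WT vehicle, edgeR recovered 13% of the 2-fold and 84% of the 4-fold changes, with 8.49% false calls. For KO ifetroban against KO vehicle these values were 39%, 92% and 9.03%. For WT ifetroban against WT vehicle they were 24%, 88% and 9.68%. For KO ifetroban against WT ifetroban they were 36%, 92% and 5.88%. For the interaction they were 5%, 67% and 12.2%, for the averaged genotype effect 67%, 99% and 4.05%, and for the averaged ifetroban effect 58%, 98% and 5.45%. DESeq2 1.42.0 on the same simulated counts made 14.8% to 26.6% false calls. It recovered more of the 2-fold changes than edgeR in each contrast, from 20% for the interaction to 83% for the averaged ifetroban effect.

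The alternatives were DESeq2, RLE in place of TMM, no low-count filter (at least 1 count in all libraries together), a stricter filter (1 CPM in at least 2 libraries), the unstranded column, the replicate number as a block, each library left out in turn, and a fit of the compared groups alone. Added after the libraries had been seen were offsets for gene length, offsets for length and GC content, a term for the class of length trend, leaving out both libraries that stood apart, and, for the covariance, 1 KO vehicle library in each effect. Length offsets lowered the largest absolute Spearman correlation of a library's deviation with gene length from 0.491 to 0.0111 in simulated counts. Comparisons that share libraries were set beside 100 simulations of unchanged groups, with fewer simulations for the covariances that left out 1 KO vehicle library. Figures were drawn with Python 3.11.15. Common-dispersion biological coefficient of variation was 0.225.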

Results

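The data were counts of reads per gene in left ventricle of wild-type (WT) mice and of mice lacking delta-sarcoglycan (KO), given vehicle or ifetroban. Delta-sarcoglycan belongs to the dystrophin-glycoprotein complex, which ties the muscle cell membrane to the surrounding matrix, and its loss causes cardiomyopathy in mice. Ifetroban is an antagonist of the thromboxane-prostanoid receptor, the product of Tbxa2r. There were 2 WT vehicle, 2 WT ifetroban, 2 KO vehicle and 3 KO ifetroban libraries. Counts in genes were 21623386 and 25452280 for WT vehicle, 26319517 and 24920107 for WT ifetroban, 21299748 and 25457889 for KO vehicle, and 21628693, 31394548 and 24436959 for KO ifetroban. The comparisons ask what the knockout changes in the ventricle, what ifetroban changes in each genotype, and whether the effect of the drug depends on the genotype.

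Sgcd (ENSMUSG00000020354, chromosome 11, 46896253 to 47988969, minus strand), the targeted gene, had 161, 304, 209, 534 and 477 reads in the KO libraries, which is 7.49 and 12.1 CPM with vehicle and 9.77, 16.4 and 18.5 CPM with ifetroban. The WT libraries held 28.9 CPM (vehicle replicate 2), 33.1 and 31.2 CPM (ifetroban), but the library labelled WT vehicle replicate 1 held 11.1 CPM from 217 reads, inside the range of the KO libraries. Sgcd therefore went against the label of that library. Among KO libraries Sgcd was lower in the 3 with long transcripts low, described below (7.49, 12.1 and 9.77 CPM), than in the other 2. The log2 difference of KO from WT was -0.21 within the former class, with 1 WT library, and -0.83 within the latter. Which exons the knockout lacks was not given in the sources used here, so the remaining reads do not show whether full-length transcript was made. Every direction drawn below from WT vehicle includes the library labelled WT vehicle replicate 1. Sgcd did not pass the test over all genes in any contrast. Its averaged genotype effect was a log2 fold change of -1.07 ± 0.292 (SE, edgeR, BH-adjusted p = 0.13). Under ifetroban alone it was -1.11 ± 0.385 (edgeR adjusted p = 0.901, and 0.0422 adjusted over the list alone). Without WT vehicle replicate 2 the averaged effect was -0.66, but that fit leaves the library labelled WT vehicle replicate 1, at 11.1 CPM, as the only one of its group.

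**Figure D1:**
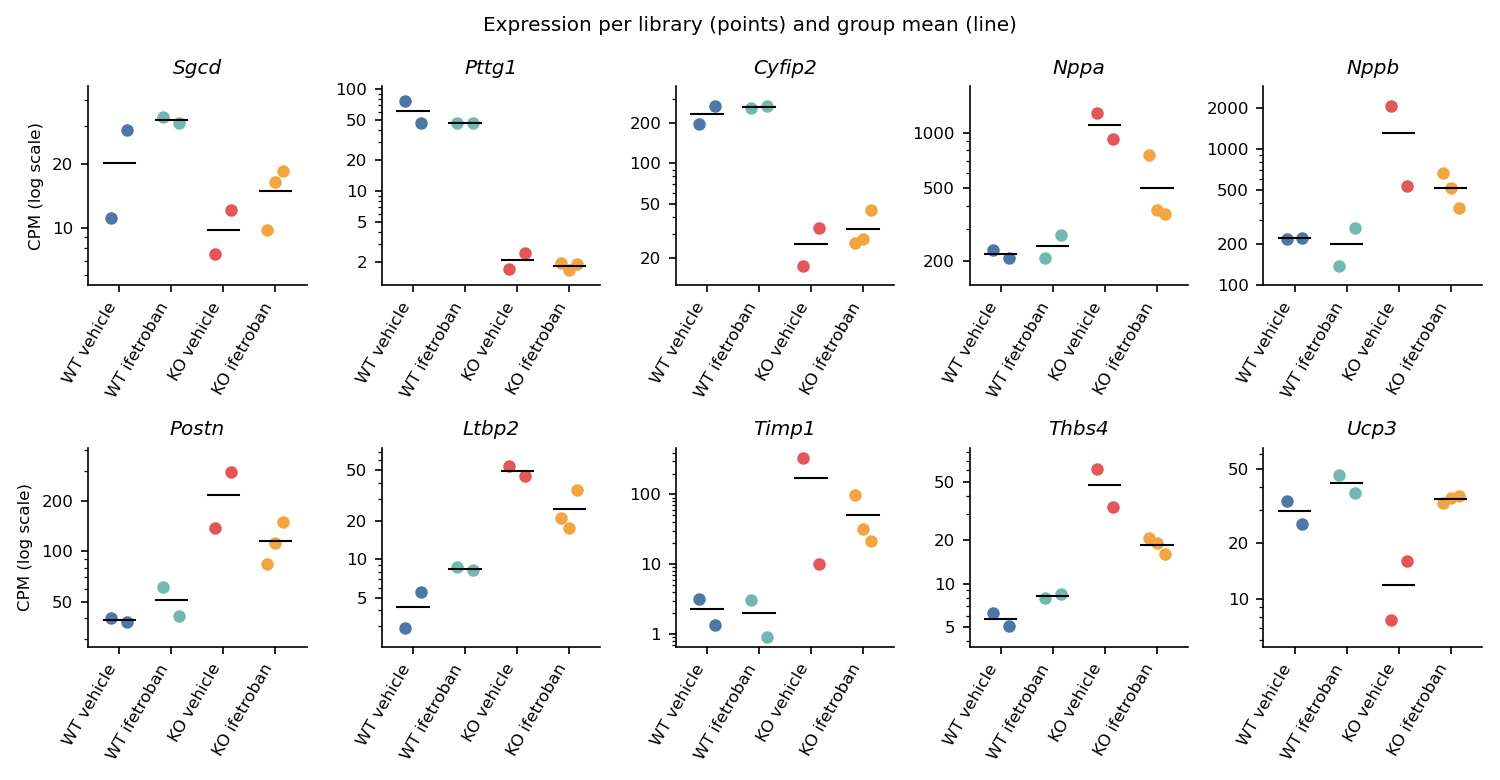
CPM on a log scale of 10 named genes in each of the 9 libraries, with points for libraries, coloured by group, and a line for each group mean. Sgcd in the library labelled WT vehicle replicate 1 (11.1 CPM) lies within the KO points (7.49 to 18.5 CPM), whereas Pttg1 in the same library (76.7 CPM) lies with the other WT libraries.

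The libraries differed in ways the groups did not explain. The first principal component held 47.5% of the variance and placed KO vehicle replicate 1 at 84.4 and KO ifetroban replicate 1 at 34.2, with the other 7 libraries between -38.2 and 2.02. KO vehicle replicate 1 carried 337 CPM of Timp1, an inhibitor of matrix proteases, against 10.1 in KO vehicle replicate 2. It also carried 143 CPM of the immediate early gene Fos and 59.7 CPM of Alb, the liver's albumin gene; these 2 genes were chosen after their values were seen. Deviations also followed transcript length. Long transcripts were low relative to short ones in 4 libraries (the library labelled WT vehicle replicate 1, both KO vehicle libraries and KO ifetroban replicate 1; Spearman -0.334 to -0.536 across genes) and high in the other 5 (0.417 to 0.491). Genes are not independent replicates, and these values describe the libraries. The trend was uneven over groups, because both KO vehicle libraries and neither WT ifetroban library had long transcripts low.

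**Figure D2:**
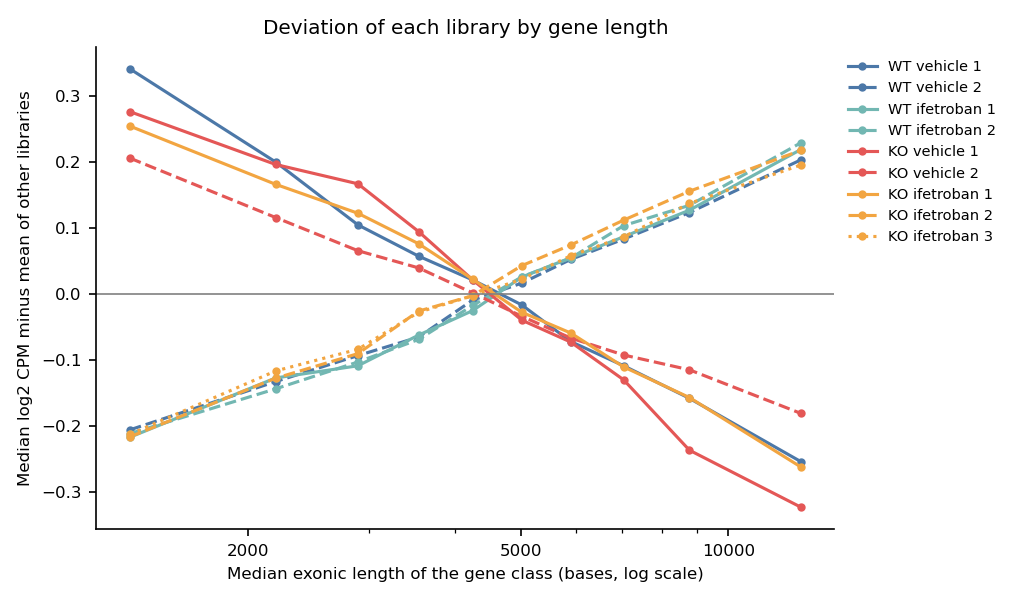
Median log2 deviation of each library from the mean of the other libraries, against the median exonic length (bases, log scale) of 10 classes of tested genes, 1 line per library coloured by group. In the longest class the library labelled WT vehicle replicate 1 lies at -0.25 and both KO vehicle libraries at -0.32 and -0.18, while WT ifetroban lies at 0.22 and 0.23.

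Without drug, the knockout ventricle had more transcripts of extracellular matrix and activated fibroblasts. All 37 tested matrix genes had positive log2 fold changes between KO vehicle and WT vehicle, with a median of 1.37. Ltbp2, a matrix protein that binds microfibrils (ENSMUSG00000002020, chromosome 12, 84783212 to 84876532), rose by 3.54 ± 0.39 (SE, edgeR, BH-adjusted p = 0.022), from 4.22 ± 1.9 to 49.6 ± 6.31 CPM (SD, n = 2 each). Thbs4, a matricellular thrombospondin (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818), rose from 5.7 ± 0.794 to 47.6 ± 19.7 CPM (adjusted p = 0.0114). The matrix list was called by camera (adjusted p = 6.54e-27; adjusted p = 0.0318 with an estimated correlation), with 3 members called over all genes and 30 when adjusted over the list alone. The third of those, Cthrc1, a secreted protein of activated fibroblasts, rose by 4.87 ± 0.639 (adjusted p = 0.0475). Of 13 myofibroblast markers 12 were positive, with a median of 1.36 (camera adjusted p = 1.07e-09; adjusted p = 0.0318 with an estimated correlation). They included Postn at 2.47 ± 0.385 and Col8a1 at 1.31 ± 0.239, neither called over all genes. Fibroblast markers had a median of 0.35, 13 of 15 positive (camera adjusted p = 7.67e-05; adjusted p = 0.256 with an estimated correlation), which was 0.65 without KO vehicle replicate 1 and 0.24, not called (adjusted p = 0.204), without KO vehicle replicate 2.

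Genes of cardiac stress moved the same way, most strongly in KO vehicle replicate 1. All 18 tested genes of the hypertrophy and fetal list were positive, with a median of 1.51 (camera adjusted p = 7.75e-10; adjusted p = 0.256 with an estimated correlation), which was 0.59 without KO vehicle replicate 1. None was called over all genes in edgeR, and 14 were higher when adjusted over the list alone. Nppa, which encodes atrial natriuretic peptide, was at 219 ± 15 CPM in WT vehicle and 1101 ± 251 in KO vehicle (log2 fold change 2.33 ± 0.365, edgeR adjusted p = 0.102), n = 2 each. Ankrd1, a stretch-responsive muscle protein, was at 831 ± 166 and 4530 ± 2354 CPM (2.45 ± 0.34, edgeR adjusted p = 0.0601). Nppb, which encodes brain natriuretic peptide, was at 221 ± 4.48 and 1306 ± 1096 CPM (2.56 ± 0.567), and at 1.27 without KO vehicle replicate 1. Ccn2, a pro-fibrotic matricellular protein, had a log2 fold change of 3.14 ± 0.65, and of 1.33 without that library. The list of endoplasmic reticulum and integrated stress (median 0.53, camera adjusted p = 0.00369; adjusted p = 0.515 with an estimated correlation) was not called without KO vehicle replicate 1 (0.00, adjusted p = 0.229) or without WT vehicle replicate 2 (0.28, adjusted p = 0.216).

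Several lists of inflammatory genes and leukocyte markers were also higher. Macrophage and monocyte markers had a median of 1.21, 19 of 22 positive (camera adjusted p = 9.96e-10; adjusted p = 0.185 with an estimated correlation). Of these 16 were higher when adjusted over the list alone and 0 over all genes in edgeR. Among them Trem2, a receptor of lipid-handling macrophages, was at 2.02 ± 0.3, and Lgals3, which encodes galectin-3, at 3.25 ± 0.584, and at 2.14 without KO vehicle replicate 1. Cytokines and chemokines had a median of 2.10, 29 of 30 positive (camera adjusted p = 1.07e-09; adjusted p = 0.265 with an estimated correlation), which was 0.46 without KO vehicle replicate 1. The chemokine gene Ccl8 was at 2.41 ± 0.61. Complement genes had a median of 0.88, 13 of 13 positive (camera adjusted p = 3.09e-09; adjusted p = 0.185 with an estimated correlation), led by the receptor gene C3ar1 at 1.16 ± 0.257. MHC class II and dendritic markers had a median of 0.96 (camera adjusted p = 4.54e-06; adjusted p = 0.265 with an estimated correlation), which was 0.42 without KO vehicle replicate 1 and 1.45 without KO vehicle replicate 2. Neutrophil markers had a median of 1.37 (camera adjusted p = 0.000511; adjusted p = 0.265 with an estimated correlation). B cell markers (-0.26, 7 of 10 negative, camera adjusted p = 0.224) and interferon genes (0.01, adjusted p = 0.529) were not called, though the latter were at 0.33 (adjusted p = 0.00977) without KO vehicle replicate 1.

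Some lists of the working cardiomyocyte went the other way, and others were not called. Of 32 genes of calcium handling and ion channels 28 were negative, with a median of -0.49 (camera adjusted p = 1.35e-06; adjusted p = 0.265 with an estimated correlation), which was -0.30 without KO vehicle replicate 1 and -0.83 without KO vehicle replicate 2. They included the potassium channel subunit gene Kcnv2 at -1.72 ± 0.36 and the pacemaker channel gene Hcn4 at -1.16 ± 0.316. Another was Atp2a2, the calcium pump of the sarcoplasmic reticulum, at -0.63 ± 0.196. Between all KO and WT libraries, the median of this list was -0.29 within those with long transcripts low and -0.08 within those with them high. Fatty acid oxidation genes had a median of -0.30, 29 of 32 negative (camera adjusted p = 4.54e-06; adjusted p = 0.265 with an estimated correlation), with Ucp3, a mitochondrial carrier, at -1.31 ± 0.307. The dystrophin-glycoprotein complex list had a median of -0.31 (camera adjusted p = 0.0395; adjusted p = 0.451 with an estimated correlation). It was not called with length offsets (-0.17, adjusted p = 0.0868), without WT vehicle replicate 2 (-0.13, adjusted p = 0.135), without KO vehicle replicate 1 (-0.15, adjusted p = 0.134) or without KO vehicle replicate 2 (-0.44, adjusted p = 0.072). Dmd, the dystrophin gene, with a long transcript, was at -0.71 ± 0.322, at -0.38 with length offsets, and at -0.43 and -0.10 within the libraries with long transcripts low and high. Sarcomere genes were not called by camera (-0.11, adjusted p = 0.255). Cardiomyocyte markers (-0.09, adjusted p = 0.152) and nuclear genes of oxidative phosphorylation (-0.09, adjusted p = 0.185) were called only with length offsets (-0.16, adjusted p = 0.00912, and -0.18, adjusted p = 5.56e-05) or without WT vehicle replicate 2 (-0.33, adjusted p = 0.00327, and -0.30, adjusted p = 1.97e-06), among these offsets and the fits that left out 1 library. Without the library labelled WT vehicle replicate 1 both turned, to 0.15 and 0.19, and were not called.

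In the prostanoid list, 16 of 20 genes were positive with a median of 0.36 (camera adjusted p = 0.0103; adjusted p = 0.225 with an estimated correlation), 0.69 without WT vehicle replicate 2 and not called without KO vehicle replicate 2 (0.45, adjusted p = 0.101). None was called over all genes and 2 were higher when adjusted over the list alone. Ptgis, prostacyclin synthase, was at 1.63 ± 0.367 and Tbxas1, thromboxane synthase, at 1.19 ± 0.379, and without KO vehicle replicate 1 at 1.07 and 0.70. Ptgs2, the inducible cyclooxygenase, was at 2.81 ± 1.05, at 0.42 without KO vehicle replicate 1 and at 4.78 without the library labelled WT vehicle replicate 1. Tbxa2r, the target of ifetroban, was low throughout, at 3.24 ± 0.445 CPM in WT vehicle and 4.87 ± 0.637 in KO vehicle (0.59 ± 0.402, edgeR adjusted p = 0.545).

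In total 6 genes rose and 2 fell between KO vehicle and WT vehicle (edgeR, BH-adjusted p under 0.05), and 1909 genes had an unadjusted p under 0.05 against 763 expected by chance. Besides those named, Dio2, which activates thyroid hormone, rose by 2.82 ± 0.353 (adjusted p = 0.0378), Frzb, a secreted Wnt inhibitor, by 2.10 ± 0.242 (adjusted p = 0.022) and Fcrls, a macrophage and microglia gene, by 1.44 ± 0.193 (adjusted p = 0.0486). Pttg1, which encodes securin, fell by 4.87 ± 0.298 (adjusted p = 0.000354) and Cyfip2, a regulator of actin assembly, fell by 3.19 ± 0.367 (adjusted p = 0.022). Of the 25 fixed genes 0 were called over all genes and 15 were higher when adjusted over the list alone, among them Col1a1 (1.10 ± 0.219) and Col3a1 (1.26 ± 0.276). Others rested on 1 library. Without KO vehicle replicate 1, Timp1 was at 2.19 instead of 6.29 ± 1.52, Spp1 at 2.92 instead of 6.07 ± 1.58 and Tgfb1 at 0.25 instead of 0.78 ± 0.272. Myh7 was at 0.23 without KO vehicle replicate 2 instead of 1.53 ± 0.527. DESeq2 called 373 genes, the edgeR fit of the 2 compared groups alone 5, and the fit with a term for the class of length trend 1. The edgeR count was 1 without the library labelled WT vehicle replicate 1, 1 without WT vehicle replicate 2, 4 without KO vehicle replicate 1, 1734 without KO vehicle replicate 2, 5 without WT ifetroban replicate 1 and 5 without WT ifetroban replicate 2. It was 3 without KO ifetroban replicate 2, 5 without KO ifetroban replicate 3 and 2 without both KO vehicle replicate 1 and the library labelled WT vehicle replicate 1.

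**Figure D3:**
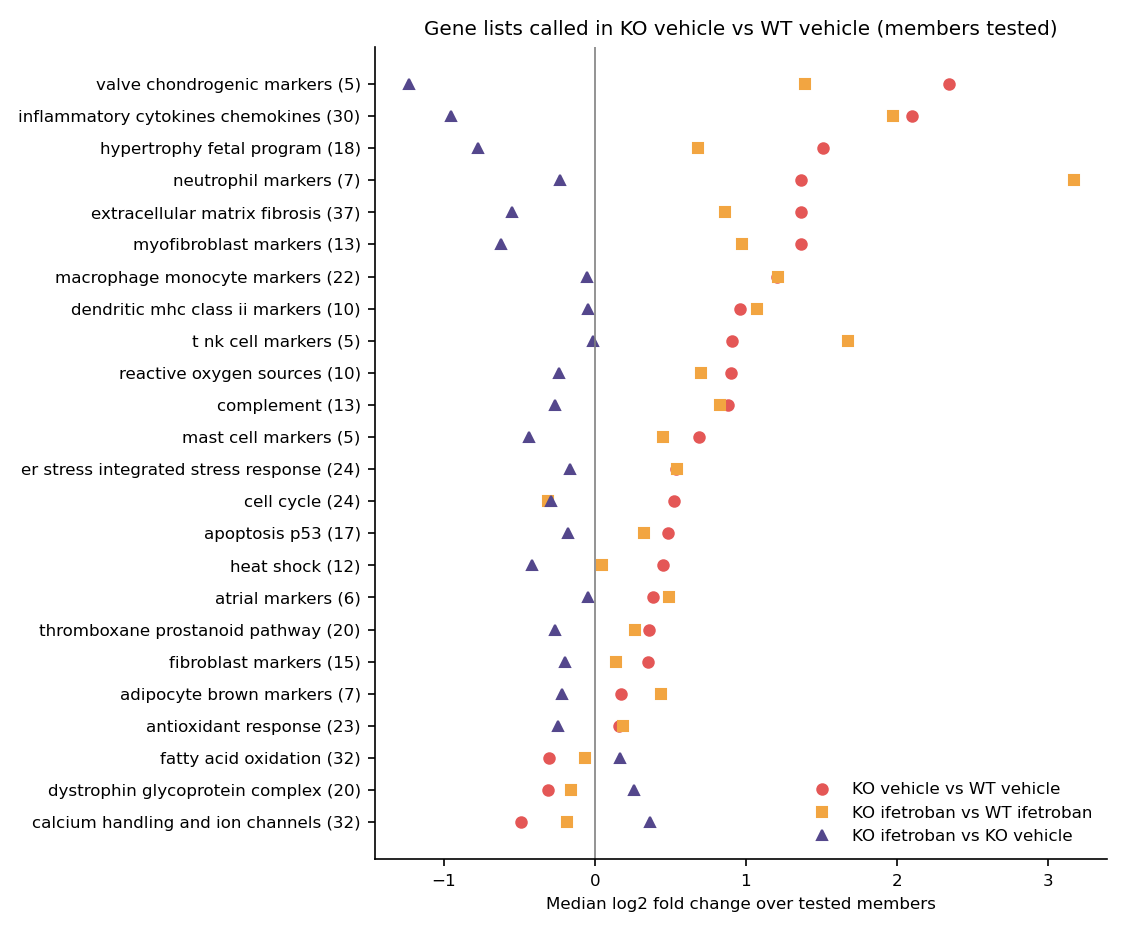
Median log2 fold change over the tested members of the 24 gene lists called between KO vehicle and WT vehicle, for that comparison (circles), KO ifetroban against WT ifetroban (squares) and KO ifetroban against KO vehicle (triangles). The matrix list lies at 1.37, 0.86 and -0.55 in these comparisons, and the calcium handling list at -0.49, -0.19 and 0.36.

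Under ifetroban the knockout ventricle still had more matrix and macrophage transcripts than the wild type. All 37 matrix genes were positive between KO ifetroban and WT ifetroban, with a median of 0.86 (camera adjusted p = 8.55e-24; adjusted p = 0.0492 with an estimated correlation) and 19 higher when adjusted over the list alone. The smallest p values in it were those of P4ha3, a collagen prolyl hydroxylase subunit (3.97 ± 0.713), Loxl1, a collagen and elastin cross-linking oxidase (0.86 ± 0.176), and the growth factor gene Tgfb2 (1.15 ± 0.251). Macrophage markers had 22 of 22 members positive with a median of 1.22 (camera adjusted p = 2.82e-19; adjusted p = 0.0583 with an estimated correlation), led by Trem2 (1.72 ± 0.282), the lysosomal protease gene Ctss (1.56 ± 0.29) and Mpeg1 (1.43 ± 0.286). Complement genes had a median of 0.83 (camera adjusted p = 9.73e-12; adjusted p = 0.0767 with an estimated correlation). Neutrophil markers had a median of 3.17, 7 of 7 positive (camera adjusted p = 3.76e-11; adjusted p = 0.122 with an estimated correlation), with Mmp8 at 3.92 ± 0.739. The hypertrophy list had a median of 0.68 (camera adjusted p = 7.5e-05; adjusted p = 0.399 with an estimated correlation), with Nppa at 243 ± 50.6 CPM (n = 2) and 501 ± 224 (n = 3). Calcium handling genes had a median of -0.19 (camera adjusted p = 0.0155; adjusted p = 0.618 with an estimated correlation), not called without KO ifetroban replicate 1 (-0.07, adjusted p = 0.242) or with length offsets (-0.12, adjusted p = 0.0955). Fatty acid oxidation genes were not called (-0.06, adjusted p = 0.113), but were with length offsets (-0.11, adjusted p = 0.0238) and without KO ifetroban replicate 2 (-0.09, adjusted p = 0.034).

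Over all genes, 0 rose and 2 fell between KO ifetroban and WT ifetroban in edgeR: Pttg1 fell by 4.65 ± 0.25 (BH-adjusted p = 0.000108) and Cyfip2 fell by 2.99 ± 0.312 (adjusted p = 0.0232). At an unadjusted p under 0.05 there were 718 genes, 588 of them higher, against 763 expected by chance, and DESeq2 called 64 higher and 5 lower. Of the fixed genes 9 were higher and 1, Sgcd, lower when adjusted over the list alone, including Ankrd1 (1.59 ± 0.312), Lgals3 (2.40 ± 0.528), Col1a1 (0.78 ± 0.202), Spp1 (5.49 ± 1.39) and Tbxas1 (1.13 ± 0.355). The count was 12 in a fit of the 2 groups alone, 8 without KO vehicle replicate 1, 8 without KO vehicle replicate 2 and 14 without both KO vehicle replicate 1 and the library labelled WT vehicle replicate 1. It was 1 with a term for the class of length trend and 1 without either WT vehicle library, either WT ifetroban library, KO ifetroban replicate 1 or KO ifetroban replicate 2, and Pttg1 was called in each of the 9 fits that left out 1 library.

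Averaged over both treatments, the knockout raised 77 genes and lowered 5 (edgeR, BH-adjusted p under 0.05; DESeq2 643 and 111). The matrix list had 16 members called and 32 higher when adjusted over the list alone, with a median of 1.11 (camera adjusted p = 5.22e-27; adjusted p = 0.0367 with an estimated correlation). The largest increases were in Sprr1a, a small proline-rich stress protein (5.96 ± 1.01, adjusted p = 0.0451), Tnc, the matrix protein tenascin C (5.06 ± 0.849, adjusted p = 0.0451), the myeloid kinase gene Fgr (3.80 ± 0.678), Hp, haptoglobin (3.42 ± 0.524), Aldh1a2, a retinoic acid synthesis enzyme (3.28 ± 0.563), and the acute-phase gene Serpina3n (3.21 ± 0.446). Lgals3 (2.83 ± 0.394), Ltbp2 (2.54 ± 0.258), the collagen cross-linking oxidase gene Lox (2.54 ± 0.334) and the lipoprotein receptor gene Lrp8 (2.49 ± 0.445) completed the 10 largest. All of these but Ltbp2 (54.1 and 45.2 CPM) were much higher in KO vehicle replicate 1 than in replicate 2. Sprr1a was at 37.3 and 2.42 CPM, Tnc at 146 and 7.43, Fgr at 9.35 and 1.19, Hp at 24.3 and 4.05 and Aldh1a2 at 85.8 and 11.9. Serpina3n was at 319 and 62.7 CPM, Lgals3 at 34.1 and 10.2, Lox at 62.2 and 17.9 and Lrp8 at 12.1 and 2.62. In WT libraries Sprr1a (0.119 to 0.345 CPM) and Fgr (0.205 to 0.384 CPM) were near the floor. Among macrophage markers 7 were called and 17 were higher when adjusted over the list alone, with a median of 1.26 (camera adjusted p = 1.49e-13; adjusted p = 0.118 with an estimated correlation), led by Trem2 (1.87 ± 0.206, adjusted p = 0.0125). Of the fixed genes, Nppa (1.68 ± 0.245, adjusted p = 0.0324), Ankrd1 (2.02 ± 0.231, adjusted p = 0.0142), Postn (1.82 ± 0.259, adjusted p = 0.0304), Col1a1 (0.94 ± 0.149, adjusted p = 0.0432), Col3a1 (1.11 ± 0.188, adjusted p = 0.0451) and Lgals3 rose. Adjusted over the list alone, 14 were higher and 3 lower, the latter being Sgcd, Myh6 (-0.52 ± 0.184) and Dmd (-0.56 ± 0.217). The genotype effects with vehicle and with ifetroban, which share no library, had a Pearson correlation of 0.638 and a Spearman correlation of 0.582 across 15261 genes, which are not independent replicates. Long transcripts were low in both KO vehicle libraries but only replicate 1 of WT vehicle, and in KO ifetroban replicate 1 but neither WT ifetroban library. The length trend thus enters both effects in the same direction, and how much of the correlation it gives was not tested.

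Of the 5 genes that fell, 4 lay near Sgcd on chromosome 11. These were Pttg1 (ENSMUSG00000020415, 43420250 to 43426251), which fell by 4.76 ± 0.198 (edgeR, BH-adjusted p = 9.43e-06), and Cyfip2 (ENSMUSG00000020340, 46193850 to 46312859), which fell by 3.09 ± 0.243 (adjusted p = 0.00185). The others were Ublcp1, a proteasome phosphatase gene (44454571 to 44470498), which fell by 0.81 ± 0.126 (adjusted p = 0.04), and Gm12167, a model annotated as antisense (46342287 to 46345020), which fell by 2.19 ± 0.297 (adjusted p = 0.0284). Gm12167 and the remaining gene, Sv2c on chromosome 13, lie outside the naming rule and were chosen after their values were seen. Pttg1 held 46.2 to 76.7 CPM in the 4 WT libraries and 1.66 to 2.46 CPM in the 5 KO libraries. Cyfip2 held 194 to 266 CPM in WT and 17.5 to 44.9 in KO libraries.

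**Figure D4:**
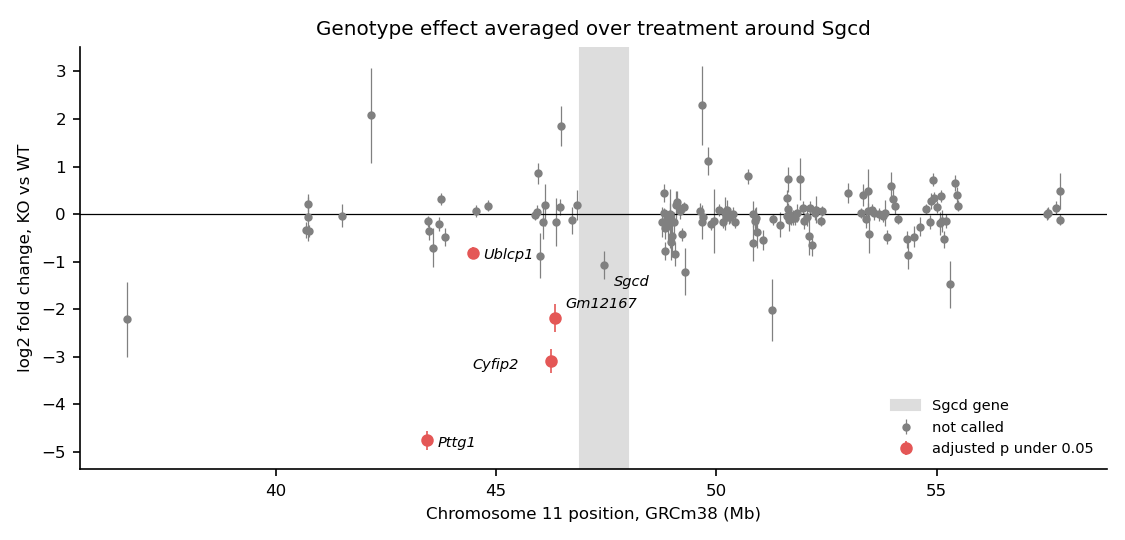
Log2 fold change between KO and WT averaged over treatment, with standard errors, of tested genes around Sgcd against their position on chromosome 11 (Mb, GRCm38), with called genes in red and the Sgcd gene as a grey band. The 4 called genes lie 0.551 to 3.47 Mb from Sgcd, and all are lower in KO.

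The averaged genotype count rested on the choice of libraries and of model. It was 3 without the library labelled WT vehicle replicate 1, 3 without WT vehicle replicate 2, 2 without WT ifetroban replicate 1, 3 without WT ifetroban replicate 2, 33 without KO vehicle replicate 1, 2098 without KO vehicle replicate 2, 22, 5 and 8 without KO ifetroban replicates 1, 2 and 3, and 25 without both KO vehicle replicate 1 and the library labelled WT vehicle replicate 1. Within the 5 libraries with long transcripts high (2 KO, 3 WT) 284 genes were higher and 60 lower, and with the class as a term 7 and 2. Both KO libraries of that class were given ifetroban and its WT libraries were of both treatments, so the first count is not balanced for treatment. The other 4 libraries hold 1 WT library and were not used for a count. Matrix genes had a median difference of 1.02 within the former libraries and 1.24 within the latter, and macrophage markers 1.12 and 1.26. Pttg1 and Cyfip2 were called in all 9 fits that left out 1 library.

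In the knockout, camera with its preset correlation gave lower matrix, hypertrophy, inflammatory and mitochondrial lists and higher ion channel and fatty acid oxidation lists with ifetroban. None of these calls held with an estimated correlation, no single gene was called over all genes by edgeR, and most of the differences rested on KO vehicle replicate 1. The hypertrophy list had a median of -0.78 between KO ifetroban and KO vehicle (camera adjusted p = 6.1e-05; adjusted p = 0.728 with an estimated correlation), 0.20 without KO vehicle replicate 1 (adjusted p = 0.528) and -1.34 without KO vehicle replicate 2. Nppa was at 1101 ± 251 CPM with vehicle (n = 2) and 501 ± 224 with ifetroban (n = 3), a log2 difference of -1.14 ± 0.313. Nppb was at -1.33 ± 0.482 and Ankrd1 at -0.86 ± 0.291, but at -0.03 and -0.20 without KO vehicle replicate 1, and Ankrd1 at -1.30 without KO vehicle replicate 2. Cytokines and chemokines had a median of -0.95 (camera adjusted p = 0.00248; adjusted p = 0.817 with an estimated correlation), which turned to 0.34 (adjusted p = 0.0481) without KO vehicle replicate 1 and was -1.67 without KO vehicle replicate 2.

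The matrix list had a median of -0.55 between KO ifetroban and KO vehicle with 3 of 37 members positive (camera adjusted p = 5.91e-06; adjusted p = 0.313 with an estimated correlation), which was -0.24 without KO vehicle replicate 1 (adjusted p = 0.00274). It included Thbs4, at 47.6 ± 19.7 and 18.5 ± 2.43 CPM (-1.36 ± 0.242, and -0.87 without KO vehicle replicate 1), the proteoglycan gene Bgn (-0.57 ± 0.169) and Ltbp2 (-1.01 ± 0.31). Among the fixed genes Col1a1 was at -0.05 ± 0.197 and Col3a1 at -0.03 ± 0.248. Myofibroblast markers had a median of -0.63, 0 of 13 positive (camera adjusted p = 0.00128; adjusted p = 0.296 with an estimated correlation), and were not called without KO vehicle replicate 2 (-0.37, adjusted p = 0.297). Immediate early genes had a median of -0.96 (camera adjusted p = 0.00248; adjusted p = 0.823 with an estimated correlation), and 0.47 without KO vehicle replicate 1, -1.58 without KO vehicle replicate 2, -1.55 without KO ifetroban replicate 1 and -0.71, not called (adjusted p = 0.0692), without KO ifetroban replicate 3. Heat shock genes had a median of -0.42 (camera adjusted p = 0.01; adjusted p = 0.817 with an estimated correlation), 0.04 without KO vehicle replicate 1 and -0.71 without KO vehicle replicate 2.

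In the other direction, calcium handling and ion channel genes had 27 of 32 members positive with a median of 0.36 between KO ifetroban and KO vehicle (camera adjusted p = 1.88e-06; adjusted p = 0.728 with an estimated correlation). It was 0.17, not called (adjusted p = 0.0543), without KO vehicle replicate 1 and 0.74 without KO vehicle replicate 2. Fatty acid oxidation genes had 24 of 32 positive, median 0.17 (camera adjusted p = 0.00248; adjusted p = 0.728 with an estimated correlation), 0.08, not called (adjusted p = 0.0651), without KO vehicle replicate 1 and 0.09 without KO ifetroban replicate 2. Among them Ucp3 was at 11.9 ± 5.88 CPM with vehicle (n = 2) and 34.6 ± 1.54 with ifetroban (n = 3), a log2 difference of 1.54 ± 0.29 and the only member higher when adjusted over the list alone, against 29.5 ± 6.04 and 41.7 ± 6.76 in the WT groups. Nuclear genes of oxidative phosphorylation were lower, 36 of 40 negative with a median of -0.21 (camera adjusted p = 0.00257; adjusted p = 0.823 with an estimated correlation), and mitochondrially encoded genes had a median of -0.27 (camera adjusted p = 0.0167; adjusted p = 0.728 with an estimated correlation). With length offsets these 2 lists were at -0.01 and 0.05, neither called. Without KO vehicle replicate 1 they were at -0.20 and -0.21 (the latter not called), without KO vehicle replicate 2 at -0.16 and -0.24 (neither called), without KO ifetroban replicate 1 at -0.40 and -0.43, and without KO ifetroban replicate 3 at -0.09 and -0.10 (neither called).

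The dystrophin-glycoprotein complex had a median of 0.26 between KO ifetroban and KO vehicle (camera adjusted p = 0.0269; adjusted p = 0.728 with an estimated correlation). It was not called with length offsets (0.12, adjusted p = 0.163), without KO vehicle replicate 1 (0.13, adjusted p = 0.276), without KO vehicle replicate 2 (0.38, adjusted p = 0.0754) or without KO ifetroban replicate 3 (0.17, adjusted p = 0.0776). Dmd was at 0.75 ± 0.299 and Utrn at 0.67 ± 0.326, at 0.31 and 0.30 with length offsets, and at 0.13 and 0.03 within the libraries with long transcripts low. B cell markers had 10 of 10 positive with a median of 0.41 (camera adjusted p = 0.00111; adjusted p = 0.296 with an estimated correlation), and 0.62 with length offsets. Macrophage markers were not called (median -0.06, camera adjusted p = 0.938), but turned to 0.27 (adjusted p = 0.0423) without KO vehicle replicate 1 and were at -0.31 without KO vehicle replicate 2. The prostanoid list was not called (-0.26, adjusted p = 0.082), except without the library labelled WT vehicle replicate 1 (-0.25, adjusted p = 0.0387) or without WT vehicle replicate 2 (-0.25, adjusted p = 0.0392), neither of them in this comparison. Tbxa2r was at 4.87 ± 0.637 and 3.23 ± 1.11 CPM.

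Over all genes edgeR called 0 between KO ifetroban and KO vehicle, with 766 at an unadjusted p under 0.05 against 763 expected by chance and a smallest BH-adjusted p of 0.688. DESeq2 called 3: Ucp3 and Pfkfb1, a bifunctional enzyme that sets fructose 2,6-bisphosphate, were higher and Thbs4 lower. The smallest p in edgeR in each direction, given as values only, belonged to Pfkfb1 (1.13 ± 0.208), Ucp3 and Armcx4 (0.92 ± 0.23), and to Thbs4, Dio2 (-1.33 ± 0.288) and Mgp, a matrix calcification inhibitor (-0.79 ± 0.19). Of the fixed genes 0 were called, over all genes or adjusted over the list alone. Without KO vehicle replicate 2 edgeR called 145 genes higher and 304 lower, and without any other library 0. Timp1 was at -1.80, at 2.30 without KO vehicle replicate 1, at -2.75 without KO vehicle replicate 2 and at -2.71 without KO ifetroban replicate 1, and Thbs4 was at -0.87 without KO vehicle replicate 1. Within the libraries with long transcripts low, 1 KO ifetroban stands against 2 KO vehicle libraries, too few for a count of calls. The median differences there were -0.52 for the hypertrophy list, -0.47 for the matrix list, -0.01 for cytokines and 0.14 for calcium handling.

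In wild type, ifetroban gave no single gene call in edgeR or DESeq2, and several of the lists that camera called rested on single libraries. Cell cycle genes had 23 of 24 members positive with a median of 0.68 between WT ifetroban and WT vehicle (camera adjusted p = 1.56e-10; adjusted p = 0.872 with an estimated correlation). The median was 0.37 without the library labelled WT vehicle replicate 1, 1.17 without WT vehicle replicate 2, 0.11, not called (adjusted p = 0.0772), without WT ifetroban replicate 1 and 1.13 without WT ifetroban replicate 2. Basement membrane genes (median 0.29, camera adjusted p = 0.0012; adjusted p = 0.92 with an estimated correlation) were at -0.04 without the library labelled WT vehicle replicate 1 and 0.68 without WT vehicle replicate 2. Nuclear genes of oxidative phosphorylation (-0.31, camera adjusted p = 1.79e-07; adjusted p = 0.92 with an estimated correlation) were at -0.04 and -0.54 without these libraries, and at -0.10 with length offsets. Erythroid markers (median -2.06, camera adjusted p = 1.69e-05; adjusted p = 0.872 with an estimated correlation) and neutrophil markers (-1.92, camera adjusted p = 3.2e-05; adjusted p = 0.872 with an estimated correlation) were at -0.91 and -0.86 without the library labelled WT vehicle replicate 1, and stayed called in each fit that left out 1 library. Immediate early genes (-0.97, camera adjusted p = 0.000181; adjusted p = 0.92 with an estimated correlation) were not called without that library (-0.16, adjusted p = 0.984) or without WT ifetroban replicate 1 (-0.90, adjusted p = 0.0534). The other 3 lists called, matrix, interferon and Schwann cell and neuronal genes, each had a camera adjusted p of 0.0449 (adjusted p = 0.92, 0.92 and 0.872 with an estimated correlation), and lost the call in fits that left out 1 library.

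Over all genes edgeR called 0 in wild type, with 192 at an unadjusted p under 0.05 against 763 expected by chance and a smallest BH-adjusted p of 0.999, and DESeq2 called 0. The shared estimate of the spread includes the more variable KO vehicle libraries, which may have made this test conservative. Given as values, the smallest p belonged to Frzb (0.96 ± 0.239), Carmil1 (0.74 ± 0.245) and Fstl4 (0.85 ± 0.31) among higher and Evi2a (-1.18 ± 0.357), Snhg14 (-0.92 ± 0.277) and Fah (-0.63 ± 0.19) among lower genes. The fixed genes gave 0 calls, also when adjusted over the list alone, with Nppa at 219 ± 15 and 243 ± 50.6 CPM, Postn at 39.1 ± 1.72 and 51.2 ± 14, and Tbxa2r at 3.24 ± 0.445 and 2.77 ± 1.18 (n = 2 each).

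The interaction asks whether the effect of ifetroban in the knockout differed from that in the wild type. No gene was called by edgeR (211 at an unadjusted p under 0.05 against 763 expected by chance; DESeq2 0), and of the fixed genes 0 passed when adjusted over the list alone. As values, the smallest p belonged to the synaptic vesicle gene Sv2a (1.41 ± 0.363), Abca4 (2.03 ± 0.534) and Pfkfb1 (1.09 ± 0.297) in the positive and Thbs4 (-1.90 ± 0.375), Frzb (-1.58 ± 0.315) and Ltbp2 (-2.00 ± 0.486) in the negative direction. Camera called 10 lists, 5 in each direction, and 0 with an estimated correlation. The smallest of those adjusted p values were 0.104 with an estimated correlation, for myofibroblast and B cell markers, and 0.107 with an estimated correlation for the matrix list.

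Across genes, the effect of ifetroban in the knockout opposed that of the genotype where both used the same KO vehicle libraries. When these were split, the direction depended on which library entered which effect. With shared libraries the log2 fold changes had a covariance of -0.165 and a Pearson correlation of -0.692 over 15261 genes. These libraries enter the effects with opposite sign, and 100 simulations of unchanged groups gave a covariance of -0.0852 (-0.0887 to -0.0812) and a correlation of -0.55. The observed covariance was -0.64 without KO vehicle replicate 2 and -0.114 without KO vehicle replicate 1, for which simulated values were -0.154 and -0.143. Without KO vehicle replicate 1 the covariance was thus weaker than that of unchanged groups. The spread between the 2 KO vehicle libraries alone gives -0.163. In a test chosen after seeing the data, 1 KO vehicle library entered the genotype effect and the other the ifetroban effect. The covariance was 0.0675 with replicate 1 in the genotype effect and -0.072 with replicate 2 there. Both lay outside the ranges from 100 simulations of unchanged groups (-0.0043 to 0.00554 and -0.00458 to 0.00722). The mean of both, -0.00224, lay within its simulated range (-0.00439 to 0.00605). By construction it is the covariance with shared libraries less the part that their spread gives, so it is no separate test. The simulations drew genes independently with the same dispersion in all groups, which these libraries did not follow. Whether an opposition remains without shared libraries was thus not decided.

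Averaged over both genotypes, ifetroban gave 0 calls in edgeR (780 at an unadjusted p under 0.05 against 763 expected by chance, smallest BH-adjusted p = 0.62), and DESeq2 called Ucp3 alone. The smallest p belonged to Ucp3 (1.02 ± 0.207), Bcl9l (0.55 ± 0.134) and Pfkfb1 (0.58 ± 0.148) among higher and Ptgds, a prostaglandin D synthase (-0.71 ± 0.2), Ak6 (-0.64 ± 0.185) and Mgp (-0.49 ± 0.142) among lower genes. Of the fixed genes 0 were called, also when adjusted over the list alone.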

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

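The 10 gene lists below differed between genotypes in their response to ifetroban, tested by camera on the interaction, a comparison set in advance. The tests of the shared libraries, split or not, and of length offsets were chosen after the result had been seen, and leaving out each library was set in advance. Median interactions on the log2 scale (ifetroban effect in KO minus that in WT) were -0.9369 for the hypertrophy list, -0.5156 for matrix, -0.9549 for cell cycle, -0.3078 for fibroblast and -0.7674 for myofibroblast genes. They were 0.2412 for fatty acid oxidation, 0.3188 for calcium handling, 0.8464 for B cell, 1.536 for neutrophil and 1.503 for erythroid genes. All 10 lost the call with an estimated correlation, the lowest adjusted p being 0.104 there. Of the 10, B cell markers alone moved by less than 1.5 times and stayed called in each fit that left out 1 library.

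Without KO vehicle replicate 1 the hypertrophy list was at 0.14 and calcium handling at 0.13, neither called, matrix at -0.27 and erythroid genes at 3.40. With KO vehicle replicate 2 left out, fibroblast (-0.03), myofibroblast (-0.65), neutrophil (1.30) and erythroid genes (0.77) lost the call, and calcium handling was at 0.58. Leaving out the library labelled WT vehicle replicate 1 ended the call for fibroblast (-0.16), neutrophil (0.62) and erythroid genes (0.32), with cell cycle at -0.60, fatty acid oxidation at 0.16 and calcium handling at 0.50. Leaving out WT vehicle replicate 2 ended the call for calcium handling (0.16), with cell cycle at -1.52. Cell cycle was at -0.42 without WT ifetroban replicate 1 and at -1.49 without WT ifetroban replicate 2, where neutrophil genes lost the call (1.19) and erythroid genes were at 2.46. Without KO ifetroban replicate 1 neutrophil genes lost the call (0.74) and fibroblast genes were at -0.18, and without KO ifetroban replicate 3 calcium handling was at 0.21 and myofibroblast genes at -1.24.

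The effect of ifetroban in the knockout and the effect of the genotype had a covariance of -0.165, and the spread between the 2 KO vehicle libraries, which enter both with opposite sign, alone gives -0.163. With 1 of these libraries in each effect, it was 0.0675 with replicate 1 in the genotype effect and -0.072 with replicate 2 there. Both lay outside the ranges simulated for unchanged groups. Their mean, -0.00224, lay within the simulated -0.00439 to 0.00605. By construction this mean follows from the -0.165 and -0.163, so it is no separate test. Without KO vehicle replicate 1, the library with the strongest stress transcripts, the covariance was -0.114, weaker than the -0.143 simulated for unchanged groups. Without KO vehicle replicate 2 it was -0.64, stronger than the simulated -0.154. With offsets for gene length it was -0.148, so the length trend does not account for it. The opposition was thus about as large as the spread between the shared libraries gives, and that spread may hold real differences between them. With 2 of them a reversal of the knockout's changes by ifetroban was neither shown nor excluded.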

How the results depend on the processing

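Results are given in the order KO vehicle against WT vehicle, KO ifetroban against KO vehicle, WT ifetroban against WT vehicle, KO ifetroban against WT ifetroban, interaction, averaged genotype and averaged ifetroban, where edgeR called 8, 0, 0, 2, 0, 82 and 0 genes. Without a low-count filter the counts were 1195, 428, 34, 428, 73, 1684 and 290, of which 1135, 382, 34, 421, 72, 1616 and 273 were genes that pass the filter. In that fit the prior degrees of freedom were infinite against 4.65, so the spread of single genes was replaced by the common trend and these calls are not relied on. The stricter filter gave 33 for averaged genotype. DESeq2 gave 373, 3, 0, 69, 0, 754 and 1, with more false calls in simulated data. The 2 compared groups alone gave 5 for KO vehicle against WT vehicle and 12 for KO ifetroban against WT ifetroban. With the replicate number as a block the counts were 45 for KO vehicle against WT vehicle and 531 for averaged genotype, and the cause was not tested. The labels give no meaning to the shared numbers, and correlations between same-numbered libraries of different groups ranged from 0.00108 to 0.478 over 12 pairs, so the block was not used elsewhere. Between groups of 2 libraries each, the value was the same for both numbers (0.0236, 0.181 and 0.00108). Those pairs are therefore not separate and mark neither number. KO ifetroban replicate 1 correlated with replicate 1 of WT vehicle (0.478) and of KO vehicle (0.352), and these 3 libraries share low long transcripts. For KO ifetroban replicate 2 and the replicates 2 of those groups the values were 0.326 and 0.0408.

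Among settings chosen after seeing the data, length offsets gave 15 for KO vehicle against WT vehicle and 131 for averaged genotype, and length and GC offsets 21 and 150. A term for the class of length trend gave 1, 1 for KO ifetroban against WT ifetroban and 9 for averaged genotype. Leaving out both KO vehicle replicate 1 and the library labelled WT vehicle replicate 1 gave 2, 14 and 25 for these comparisons. Leaving out 1 library at a time gave 1 to 1734, 0 to 449, 0 to 0, 1 to 8, 0 to 0, 2 to 2098 and 0 to 0 calls. The highest value in KO vehicle against WT vehicle, KO ifetroban against KO vehicle and averaged genotype came without KO vehicle replicate 2, which leaves KO vehicle replicate 1 as the only library of its group and its spread unmeasured.

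Camera called 24, 15, 9 and 10 lists for KO vehicle against WT vehicle, KO ifetroban against KO vehicle, WT ifetroban against WT vehicle and the interaction. With an estimated correlation it called 2, 0, 0 and 0, and fry called 5, 0, 0 and 0. Leaving out 1 library gave 18 to 24, 9 to 16, 6 to 9 and 10 to 14 lists. The covariance of the ifetroban effect in the knockout with the genotype effect was -0.145 with the stricter filter, -0.148 with length offsets, -0.147 with length and GC offsets, -0.139 without both named libraries, -0.00224 with 1 KO vehicle library in each effect (also chosen after seeing the data) and -0.64 to -0.114 without 1 library. Over 220 results for named genes and 4301 values, 3934 stayed on the same side of the adjusted p threshold, 191 lost a call, 176 gained one, and 0 changed sign among values called in either fit. Results that were not called did change sign, and 60 of the 220 results had another sign without some 1 library. Samples that stand apart within a group were not tested by a rule, because no group has enough libraries.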

Other observations

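Reactive oxygen sources (median log2 fold change 0.90, camera adjusted p = 0.00528; adjusted p = 0.256 with an estimated correlation) and valve and chondrogenic markers (2.34, camera adjusted p = 0.000373; adjusted p = 0.228 with an estimated correlation) were higher in KO vehicle than in WT vehicle. The former was at 0.36 without KO vehicle replicate 1, and the latter at 1.42 without the library labelled WT vehicle replicate 1 and 4.02 without WT vehicle replicate 2. Epicardial and mesothelial markers were not called there (-0.08, camera adjusted p = 0.151), except without WT vehicle replicate 2 (2.98, adjusted p = 0.000169), and were higher under ifetroban (1.11, camera adjusted p = 0.00396; adjusted p = 0.422 with an estimated correlation), but not without KO ifetroban replicate 2 (0.30, adjusted p = 0.104). Skeletal muscle markers stood at 2.31 above the mean of libraries in KO ifetroban replicate 3, and were not called with all libraries. Between KO ifetroban and WT ifetroban (median 1.89, camera adjusted p = 0.094) they were called in 8 of the 9 fits that left out 1 library, with adjusted p from 0.00357 to 0.049. Without KO ifetroban replicate 3 the median was -0.07 (adjusted p = 0.982), so the difference rested on that library.

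The libraries were regrouped within treatments for the averaged genotype effect and within genotypes for the averaged ifetroban effect, in 60 ways each. The averaged genotype effect on genes (82 calls) was reached by 1 of 60, the real grouping, and the highest other grouping gave 2. Its count at an unadjusted p under 0.05, 2518, was reached by 3 of 60 groupings, with a highest other value of 2869, so for that count chance was not excluded. For gene lists, 4 of 60 groupings reached the 25 real calls, with a highest other value of 27, so the number of lists called could arise by chance. By list, the camera p of the real grouping was reached by 1 of 60 for macrophage markers, 2 for matrix and 5 for hypertrophy. It was reached by 10 for calcium handling, 10 for fibroblast markers and 13 for fatty acid oxidation genes. For ifetroban averaged over genotypes the real grouping gave 0 calls, which any grouping reaches (60 of 60, the highest other 4), so nothing about chance follows. Its 780 genes at an unadjusted p under 0.05 were reached by 14 of 60 groupings, and its 8 called lists by 51 of 60. For these counts chance was not excluded.

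Sgcd in the library labelled WT vehicle replicate 1 was at the level of the knockout. A rule set in advance went against a label swapped with a KO sample, but it rested on only 3 genes, those called for genotype without this library. Of these, 100% lay nearer the other WT libraries in it, among them Pttg1 (76.7 CPM against 1.66 to 2.46 in KO libraries) and Cyfip2 (194 against 17.5 to 44.9). Both named genes lie near Sgcd on chromosome 11, so they are not independent of each other. Of the 100 genes with the smallest p without it, 74% lay nearer WT, and with the other libraries left out in turn this was 92% to 93% for WT, 54% for KO vehicle replicate 2 and 3% to 15% for the other KO libraries. On this wider set the library stood less clearly with WT than the other WT libraries did. The length trend was also tested by a rule set in advance, and 0.269% of 743 genes of similar length and level fell as far as Sgcd did (-1.47; median -0.25), against this trend as the whole cause. Sgcd also followed the class of length trend among KO libraries, so the trend may contribute, and what else lowered Sgcd there stayed open.

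Genes lower in the knockout lay close to Sgcd on chromosome 11, and the tests of position and of length offsets were chosen after this had been seen. Of 5 lower calls 4 lay within 10 Mb, where 138 of the tested genes (0.904%) lie (one-sided Fisher p = 3.18e-08, which restates the clustering that prompted it). With length offsets 4 of 4 kept their call. Of the higher calls 0 lay there, which at so small a share of genes gives no contrast with the lower calls. Linked DNA of another strain around the targeted gene could give such clustering, but an effect of the targeted allele itself on its neighbours was not excluded. By a rule set in advance, a response to disease severity required variation among KO libraries at least as large as in the matrix list. The ratio of highest to lowest KO CPM had a median of 2.02 in these genes and 2.26 in the matrix list, so the rule went against it. The ratios overlapped (1.2 to 3.16 in these genes, quartiles of 1.71 and 3.87 in the matrix list), so such a response was not excluded. The strain was not given in the sources used here.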
